A study of Arabidopsis thaliana with 21 samples.

How the data were processed

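RNA was measured in 21 libraries of hand-dissected Arabidopsis embryos at the late heart stage, 3 biological replicates for each of 7 genotypes. Per the labels' protocols, embryos were washed and concentrated on Percoll, and libraries were made from 70 to 90 ng of total RNA with a Nugen Ovation kit. Plants grew at 22 °C with 16 h of light. The values used are read counts per gene model, deposited as 1 table per library, which lists only models with reads. Bowtie 0.12.7, edgeR 3.0.8 and the genome build TAIR10 are named per the submitters' processing notes. The counting rule, the treatment of reads that map to several places and the strand are not given in the sources used here. Overlapping and near-identical genes can therefore share reads.

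The tables were joined into 26496 models, with 0 where a model was not listed. Of these, 26100 matched a locus tag of the TAIR10.1 annotation, which gives the coordinates, and 396 did not. Totals ran from 1.49 M (1000000 counts), in asil1-1 asil2-2 replicate 2, to 8.19 M, in asil2-2 replicate 1. Pairs of replicates were checked for copied libraries, and none of 21 pairs was identical.

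Groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. All 21 libraries entered 1 model with 7 groups in edgeR 4.0.16 (R 4.3.3). Models with low counts were removed with filterByExpr by group (minimum count 10, minimum total 15), which left 18269. Libraries were scaled by TMM. Each comparison was a contrast tested with edgeR's quasi-likelihood test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The double mutant asil1-1 asil2-2 was called only where it passed against both Col-0 and Ler in the same direction, with the higher p taken and the fold change nearer 0 given. CPM values use TMM-scaled library sizes, and log2 CPM adds a prior count of 2. Standard errors of log2 fold changes are approximations, the fold change divided by the square root of the F statistic. Given ratios against a group with 4 counts or fewer are count ratios with an exact 95% interval, and those against a group at 0 use a floor of 3 counts over the group.

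The 21 gene lists, with 374 loci, were tested in each of the 6 group comparisons with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested genes). An estimated correlation and fry were run beside it. Adjusted over the list alone means that Benjamini-Hochberg was applied to the members of that list only. Shared calls were compared with the overlap of independent lists and with 20 simulations of unchanged groups against the same controls.

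Genes were named by rule. They are ASIL1 and ASIL2 in every comparison and up to 6 of the largest rises and falls per group comparison. The latter needed an adjusted p under 0.05, a mean log2 CPM of at least 2 and every mutant library beyond every wild-type library, which chance gives in 10% of genes with 3 against 3. Up to 4 changed members of each list and the 5 genes with the lowest adjusted p in the interaction and the allele contrast were also named. List members that passed over their list alone, the further rises of asil1-1 asil2-2 and AT3G27473 were named after their values were seen. Of the genes that the rule names between the wild types, part are given here.

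Alternatives were RLE scaling, no filter on low counts, a replicate block, a fit of only the compared groups, DESeq2 1.42.0, both other list tests and each library left out in turn. Leaving out the 2 libraries that stand apart and limma-voom with library weights were added after the data were seen. Other splits of the samples were counted for every comparison, with 60 drawn where there were more. A longer first draw was shortened for time after its counts had been seen.

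The scripts that test many genes were tested on simulated data in which 200 genes, drawn from those with a mean of at least 4 CPM, changed by 2-fold or 4-fold. Of these, 58% and 99% were recovered for asil1-1, 51% and 94% for asil2-1, 49% and 96% for asil2-2, 63% and 89% for asil1-1 asil2-1 and 41% and 86% for asil1-1 asil2-2. For Ler against Col-0 they were 54% and 98%, for the interaction 23% and 81% and for the allele difference 20% and 72%. A 2-fold change can thus be missed, and recovery was not measured for genes under 4 CPM. All simulated libraries were drawn with the same spread for a gene, so none stood apart as 2 real ones do. The shares recovered may therefore not hold for the real libraries. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.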

Results

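RNA was sequenced from Arabidopsis thaliana embryos at the late heart stage, when the cotyledons emerge. Per the labels, the embryos carried mutations in ASIL1, ASIL2 or both, genes of 2 trihelix DNA-binding proteins known as repressors of the seed maturation programme. The 21 libraries fall into 7 genotypes with 3 biological replicates each. They are the wild types Columbia-0 (Col-0) and Landsberg erecta (Ler), the single mutants asil1-1 and asil2-1 in Col-0 and asil2-2 in Ler, and the double mutants asil1-1 asil2-1 in Col-0 and asil1-1 asil2-2 in a mixed background. Read counts for 26496 gene models were deposited, and 18269 models passed the filter on low counts and were tested.

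Total counts, in M (1000000 counts) for replicates 1, 2 and 3, were 4.32, 5.77 and 4.54 in Col-0, 5.23, 4.99 and 5.41 in Ler, and 5.69, 8.05 and 7.74 in asil1-1. They were 6.20, 4.81 and 5.84 in asil2-1, 8.19, 6.84 and 6.16 in asil2-2, 4.14, 5.46 and 6.92 in asil1-1 asil2-1, and 5.78, 1.49 and 5.74 in asil1-1 asil2-2. In replicate 1 of asil1-1 asil2-1 the locus AT5G18610 took 45.7% of all counts, while no locus took more than 3.88% in any of the other 20 libraries. That library's log2 CPM (counts per M counts) correlated with the others at 0.683 to 0.76, across genes, which are not independent replicates. Replicate 2 of asil1-1 asil2-2, the shallowest library, had a median correlation of 0.851 with the others, below the 0.934 to 0.967 of the remaining 19. Counts of called genes are therefore also given without these 2 libraries that stand apart, a setting chosen after the data were seen.

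The targeted genes were examined first, in every library. ASIL1 (AT1G54060, chromosome 1, 20180610 to 20182374, TAIR10.1) lay between 1.28 and 5.75 CPM in the 9 libraries carrying asil1-1 and between 32.4 and 67.8 CPM in the 12 others. It fell by 4.48 ± 0.26 (log2, SE) in asil1-1, by 3.25 ± 0.25 in asil1-1 asil2-1 and by 3.12 ± 0.25 in asil1-1 asil2-2. In asil2-2 against Ler, ASIL1 was higher by 0.57 ± 0.19, with every asil2-2 library above every Ler library, but did not pass the test. ASIL2 (AT3G14180, chromosome 3, 4706802 to 4709176, TAIR10.1) was at most 13.5 CPM in the 6 libraries carrying asil2-2, against at least 37.5 CPM in all others, and fell by 2.41 ± 0.32 in asil2-2 and by 2.78 ± 0.35 in asil1-1 asil2-2. In the libraries labelled asil2-1, ASIL2 did not pass the test. It measured 41.8 ± 5.59 CPM in asil2-1 and 50.9 ± 9.77 in asil1-1 asil2-1 against 51.2 ± 4.2 in Col-0 (SD, n = 3 each), with log2 fold changes of -0.29 ± 0.30 and 0.00 ± 0.30. The lesion of each allele is not given in the sources used here, so ASIL2 counts do not check the asil2-1 label. The adjusted p of these falls in edgeR's quasi-likelihood test ranged from 9.42e-10 to 0.0013 after Benjamini-Hochberg adjustment, and those of ASIL2 with asil2-1 were 1 and 0.995.

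**Figure D1:**
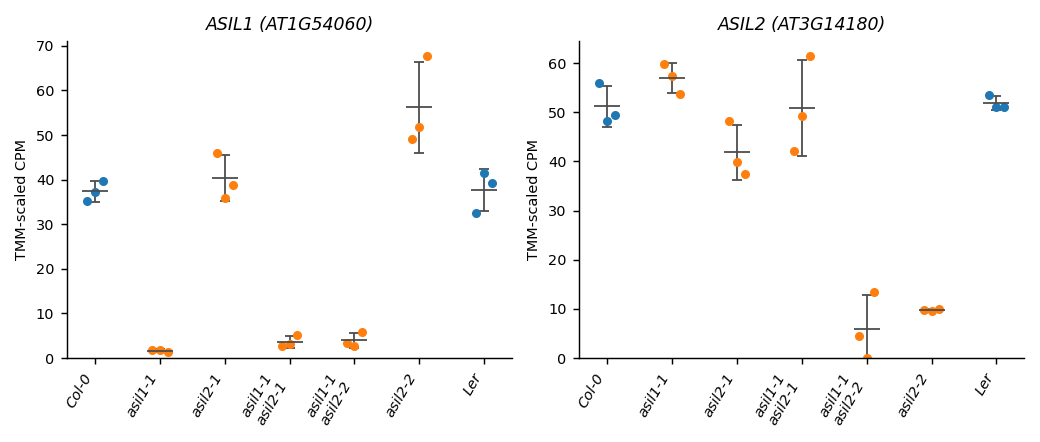
TMM-scaled CPM of ASIL1 (left) and ASIL2 (right) in each library, by genotype; points are libraries (wild types blue, mutants orange), and the horizontal line and bars are the mean and SD of 3. ASIL1 is at most 5.753 CPM wherever asil1-1 is carried, ASIL2 stays under 13.5 CPM wherever asil2-2 is carried, and ASIL2 keeps 37.5 CPM or more with asil2-1.

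Loss of ASIL1 alone was examined in asil1-1 against Col-0. FER2 (AT3G11050), a ferritin that stores iron in seeds, was 34.0 ± 4.16 CPM in asil1-1 and 8.14 ± 1.06 CPM in Col-0 (SD, n = 3 each), a log2 rise of 2.07 ± 0.20 (SE). AT1G62060, an uncharacterized gene, rose by 3.21 ± 0.58, LRB3 (AT4G01160), a BTB-domain protein, by 1.82 ± 0.33, and TBL38 (AT1G29050), of the TRICHOME BIREFRINGENCE-LIKE family of cell wall proteins, by 1.43 ± 0.22. AT5G14580, a polyribonucleotide nucleotidyltransferase that trims organelle RNA, rose by 1.06 ± 0.19. ASIL1 itself was the only gene that fell. edgeR's quasi-likelihood test thus called 5 rises and 1 fall at a Benjamini-Hochberg adjusted p under 0.05, with 453 genes at an unadjusted p under 0.05. The latter number is less than the share of 0.05 of the 18269 tested genes that chance alone would give. It was 1378 without the 2 libraries that stand apart, above that share of the 18332 genes then tested. The low number therefore does not show that no other genes differ. Adjusted p was 4.93e-06 for FER2, 0.00759 for TBL38 and 0.0492 for AT1G62060, LRB3 and AT5G14580. Without the 2 libraries that stand apart there were 34 rises and 1 fall, the 6 calls above among them. Leaving out any 1 of the 6 compared libraries left 2 to 4 calls, always with ASIL1 and FER2. LRB3 and AT5G14580 were then lost each time, AT1G62060 except without asil1-1 replicate 1, and TBL38 without asil1-1 replicate 3 or any Col-0 library, and over all alternatives their highest adjusted p were 0.501, 0.596, 0.841 and 0.129.

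Among the 21 gene lists fixed beforehand, 6 were called in asil1-1. Of the 10 splits of the same libraries, 2 called 6 lists, the real one included. Of 10 measured genes of auxin synthesis and response, 8 were lower, with a median log2 fold change of -0.53, and GH3.1 (-0.86 ± 0.27) and GH3.3 (-0.61 ± 0.21), enzymes that conjugate auxin, fell when adjusted over the list alone, though none did over all genes. This list had a camera adjusted p of 0.000161 with the preset correlation and was the only call to hold with an estimated one, at 0.0102, though not without the 2 libraries that stand apart (adjusted p = 7.03e-05, and adjusted p = 0.055 with an estimated correlation). Genes of wound, touch and cold response were lower in 13 of 14 (median -0.31, adjusted p = 8.8e-05, and adjusted p = 0.368 with an estimated correlation). Adjusted over the list alone, 1 of them fell, DREB2A, a transcription factor of drought and heat response, by 0.84 ± 0.24, and none over all genes. Ler was also lower than the same Col-0 libraries in 8 of 10 auxin genes and in 14 of 14 genes of this list. The level of the Col-0 libraries may therefore be part of both shifts. Light harvesting and photosystem genes were higher in 33 of 34 by a median of 0.10 (adjusted p = 0.000279, and adjusted p = 0.437 with an estimated correlation), and none passed the test, over all genes or adjusted over the list alone. Embryo patterning and meristem genes were lower in 28 of 39 (median -0.16, adjusted p = 0.0041, and adjusted p = 0.437 with an estimated correlation), none of them called either way, and this call was lost without asil1-1 replicate 3 (adjusted p = 0.168) or Col-0 replicate 3 (0.078), reaching 0.602 over all alternatives. The call of the trihelix list (adjusted p = 0.00464, and adjusted p = 0.0627 with an estimated correlation) held ASIL1 as its only changed member, with a median of 0.00 over 18 genes, and was lost without asil1-1 replicate 2 (adjusted p = 0.0635), reaching 0.66 over all alternatives.

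Seed coat markers, fixed as a list of tissue that dissected embryos could carry along, went both ways in asil1-1. Adjusted over the list alone 5 of 15 rose and none over all genes. They were PMEI6 (AT2G47670, 2.85 ± 0.62), DP1 (AT4G11180, 2.38 ± 0.75), PER36 (AT3G50990, 2.07 ± 0.47) and MUM4 (AT1G53500, 0.74 ± 0.19), which act in or mark the mucilage-secreting outer layer, and TT10 (AT5G48100, 0.56 ± 0.18), a laccase of flavonoid oxidation. PMEI6 and DP1 started from low levels, with means of 0.404 and 1.18 CPM in Col-0. Of the 10 other members 9 were lower, so that the list's median was -0.13 while its mean, 0.28, and its camera call pointed up (adjusted p = 0.0454, and adjusted p = 0.404 with an estimated correlation). The call was lost without asil1-1 replicate 1 (adjusted p = 0.0731), asil1-1 replicate 3 (0.272) or Col-0 replicate 3 (0.336), as well as without the 2 libraries that stand apart (0.104), and its highest adjusted p over all alternatives was 0.479. Endosperm markers were not called, with 7 of 13 higher and an adjusted p of 0.554. Genes that act in maturation itself did not pass the test in asil1-1. Of the seed maturation activators, 10 of 15 were higher (adjusted p = 0.326), of the seed storage proteins 2 of 6 (0.714), and of the oil body and storage lipid genes 6 of 15 (0.723), and none was called over all genes or adjusted over the list alone.

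**Figure D2:**
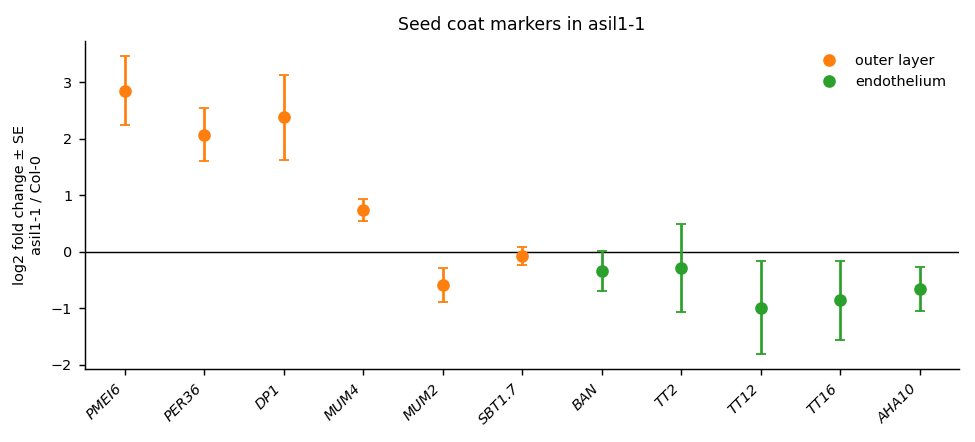
Log2 fold change (asil1-1 over Col-0, bars are SE, 3 libraries each) of markers of the outer seed coat layer (orange) and of the endothelium, its innermost layer (green); this division into layers was made after the values were seen. PMEI6, DP1, PER36 and MUM4 lie between 0.74 and 2.85, while MUM2, SBT1.7 and the 5 endothelium markers lie at or below -0.08. TT10, which rose when adjusted over the list alone, and further members of the seed coat list are not shown.

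The asil2-1 embryos differed from Col-0 in 2 genes, both lower. G6PD3 (AT1G24280), a plastid glucose-6-phosphate dehydrogenase, was 6.51 ± 1.53 CPM against 25.8 ± 3.15 in Col-0 (SD, n = 3 each) and fell by 1.99 ± 0.31 (log2, SE). UBC11 (AT3G08690), a ubiquitin-conjugating enzyme, was 23.2 ± 0.789 CPM against 58.4 ± 0.776 and fell by 1.33 ± 0.20. Both had an adjusted p of 0.0153 in edgeR's quasi-likelihood test, with 316 genes at an unadjusted p under 0.05 and no gene that rose. These 316 are less than the share of 0.05 of the 18269 tested genes that chance alone would give. The 1212 without the 2 libraries that stand apart were above that share of the 18332 then tested. DESeq2 called 4 genes. Neither call held with any 1 of the 6 libraries left out (0 calls each time). Without the 2 libraries that stand apart there were 3 calls, all lower, G6PD3 (adjusted p = 1.65e-05), UBC11 (9.34e-07) and DREB2A (-1.32 ± 0.21, 0.0265), and over all alternatives the adjusted p of G6PD3 and UBC11 reached 0.343. ASIL2 lay lower in each of the 3 libraries labelled asil2-1 than in each Col-0 library but did not pass the test (-0.29, adjusted p = 1), so no direction here can be ascribed to a loss of its transcript. In asil1-1 asil2-1, G6PD3 was at 7.804, 21.21 and 24.13 CPM in replicates 1, 2 and 3, against 23 to 29.23 in Col-0. Replicate 1 there is a library that stands apart, so the low level of G6PD3 was not seen in the rest of that genotype. In asil2-2, G6PD3 was at 22.88 to 28.46 CPM, against 23.87 to 31.32 in Ler.

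Several lists shifted slightly in asil2-1, with no member called over all genes. Light harvesting and photosystem genes were higher in 33 of 34 (median 0.13, adjusted p = 3.21e-06, and adjusted p = 0.425 with an estimated correlation), cell cycle and cytokinesis genes in 21 of 26 (0.0124, and adjusted p = 0.611 with an estimated correlation), oil body and storage lipid genes in 12 of 15 (0.0226, and adjusted p = 0.425 with an estimated correlation) and seed maturation activators in 12 of 15 (0.0306, and adjusted p = 0.425 with an estimated correlation). None of these members passed when adjusted over the list alone. All 8 heat shock genes were lower (median -0.64, adjusted p = 0.000104, and adjusted p = 0.425 with an estimated correlation). DREB2A, of the wound, touch and cold list (9 of 14 lower, adjusted p = 0.00949, and adjusted p = 0.486 with an estimated correlation), fell by 1.32 ± 0.24 when adjusted over the list alone, as did GH3.1 (-0.87 ± 0.27) and GH3.3 (-0.60 ± 0.21) of the auxin list (5 of 10 lower, median -0.09, 0.0198, and adjusted p = 0.221 with an estimated correlation). SPL factors and microRNA machinery were lower in 10 of 12 (0.0311, and adjusted p = 0.486 with an estimated correlation). The asil1-1 and asil2-1 comparisons share the Col-0 libraries, and GH3.1 and GH3.3 fell alike in both. Ler was also lower than Col-0 in 8 of 10 auxin genes (median -0.46, not called) and 14 of 14 wound, touch and cold genes. For these 2 lists the level of the Col-0 libraries cannot be told apart from an effect of the mutations. Heat shock genes were lower than in Col-0 in 8 of 8 in Ler and, without a call, in 8 of 8 in asil1-1 (median -0.45), but higher in asil1-1 asil2-1 in 8 of 8. Light harvesting genes were higher in 33 of 34 in asil1-1 as well, but lower in Ler in 30 of 34. The level of the Col-0 libraries may be part of these shifts too. Without Col-0 replicate 3 only the light harvesting list was called, which no left-out library ended. There were 4 called lists without asil2-1 replicate 1 or Col-0 replicate 2, 5 without asil2-1 replicate 2, 7 without asil2-1 replicate 3 and 9 without Col-0 replicate 1, and over all alternatives the adjusted p of the other 7 lists reached 0.463 to 0.847.

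Loss of ASIL2 was examined in Ler, with asil2-2, where 8 genes rose and 5 fell. AT2G34655, an uncharacterized gene, was 36.1 ± 2.94 CPM in asil2-2 (SD, n = 3) and had 2 counts over the 3 Ler libraries, a 283-fold ratio with a 95% counting interval of 78.1 to 2340. The putative dioxygenase 2A6 (AT1G03410) rose by 4.22 ± 0.26 (log2, SE), from 1.07 ± 0.375 CPM in Ler to 20.4 ± 3.12. NEK3, a protein kinase, rose by 1.60 ± 0.23, RAV2 (AT1G68840), a B3 and AP2 domain repressor of flowering, by 1.5 ± 0.27, the actin-bundling VLN5 by 1.47 ± 0.27, AT4G14730, of the Bax inhibitor-1 family, by 1.46 ± 0.27, and the Calvin cycle gene GAPB by 1.02 ± 0.17. Besides ASIL2, the falls were DDB1B, an adaptor of ubiquitin ligases, by 1.92 ± 0.28, AGD9 by 1.12 ± 0.15, MYC3, a jasmonate-response factor, by 1.02 ± 0.15, and HDG2, an epidermal homeodomain factor, by 0.99 ± 0.17. AT3G27473, named after its values were seen, also rose, but its level was under the minimum for naming genes.

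In 7 of the 12 calls other than ASIL2, the Ler libraries lay beyond all 18 others, Col-0 and its mutants included. For 2A6 the 18 ranged from 17.5 to 35.1 CPM and for AGD9 from 39.8 to 69.5 CPM, against 133 ± 10.8 in Ler. edgeR's quasi-likelihood test gave an adjusted p of 2.5e-09 for 2A6, 0.00125 for AGD9 and at most 0.0368 for the rest, with 471 genes at an unadjusted p under 0.05. These 471 are less than the share of 0.05 of the 18269 tested genes that chance alone would give. The 1459 without the 2 libraries that stand apart were above that share of the 18332 then tested. Without the 2 libraries that stand apart, 27 genes rose and 21 fell, including all 13 above. Leaving out 1 library at a time left 10 calls without asil2-2 replicate 2, 8 without replicate 3 and 6 without replicate 1, and 5, 6 and 7 without Ler replicates 1, 2 and 3. ASIL2, 2A6, AGD9, MYC3 and DDB1B were always kept, NEK3 was lost only without Ler replicate 1 (adjusted p = 0.053) and GAPB with any library left out. Over all alternatives the adjusted p of GAPB, HDG2, RAV2, VLN5, AT4G14730 and AT2G34655 reached 0.205, 0.205, 0.367, 0.243, 0.473 and 0.205. Of the lists, carbon fixation was higher in 6 of 8 (adjusted p = 0.00772, and adjusted p = 0.68 with an estimated correlation), where GAPB was the only member to rise, over all genes and adjusted over the list alone. Heat shock genes were lower in 8 of 8 (median -0.63, adjusted p = 0.00772, and adjusted p = 0.729 with an estimated correlation), none of them called. Without asil2-2 replicate 3 neither list was called (adjusted p = 0.0949 for both). Carbon fixation was also lost without asil2-2 replicate 1 (0.0861) or Ler replicate 2 (0.0814) and heat shock without Ler replicate 3 (0.113) or the 2 libraries that stand apart (0.0555), and over all alternatives their adjusted p reached 0.705 and 0.812. Seed storage proteins were higher in 5 of 6 without a call (adjusted p = 0.57). Of the 10 splits of the same libraries, 8 called 2 lists or more, the real one included.

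The difference between the responses to the alleles of ASIL2 was itself tested, as asil2-1 against Col-0 minus asil2-2 against Ler. Only 2A6 passed, with a difference of -4.10 ± 0.32 (log2, SE, adjusted p = 3.05e-07, edgeR quasi-likelihood). Its level was 26.6 ± 2.54 CPM in Col-0, 28.8 ± 3.96 in asil2-1, 20.4 ± 3.12 in asil2-2 and 1.07 ± 0.375 in Ler (SD, n = 3 each), so Ler was the group apart. AGD9 (1.24 ± 0.21, adjusted p = 0.0502), NEK3 (-1.72 ± 0.32, 0.14), MYC3 (1.10 ± 0.21, 0.161) and UBC11 (-1.40 ± 0.27, 0.161) did not pass. There were 301 genes at an unadjusted p under 0.05, less than the share of 0.05 of the 18269 tested genes that chance alone would give. The 1094 without the 2 libraries that stand apart were above that share of the 18332 then tested. Without the 2 libraries that stand apart, 5 differences above and 6 below 0 passed. Without asil2-2 replicate 3 the count was 2, and 2A6 was kept whichever library was left out.

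Of the double mutants, the libraries labelled asil1-1 asil2-1, where ASIL1 fell but ASIL2 stayed near the Col-0 level (0.00), were compared with Col-0. FER2 rose by 2.09 ± 0.20 (log2, SE), to 35.0 ± 8.91 CPM (SD, n = 3), and DI21 (AT4G15910), a drought-induced gene, rose by 1.00 ± 0.14, from 90.2 ± 11.3 to 181 ± 39.0 CPM. UBC11 fell by 1.34 ± 0.20 and was between 10.9 and 28.2 CPM in all 6 libraries carrying asil2-1, against 51.1 to 69.1 CPM in the 15 others. With ASIL1, these are the 2 rises and 2 falls that edgeR's quasi-likelihood test called, with adjusted p of 5.26e-06 for FER2, 0.0029 for DI21 and 0.00559 for UBC11, and 2942 genes at an unadjusted p under 0.05. Replicate 1 of this genotype is the library in which AT5G18610 took 45.7% of the counts. Without the 2 libraries that stand apart 17 genes rose and 9 fell, the 4 calls among them, and the count was 10 without asil1-1 asil2-1 replicate 1, 122 without replicate 2, 239 without replicate 3 and 2 without Col-0 replicate 1, where DI21 (adjusted p = 0.0574) and UBC11 (0.0527) were lost. In a fit of only the compared groups no gene was called, and over all alternatives the adjusted p of FER2, DI21 and UBC11 reached 0.346, 0.699 and 0.699.

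Embryo patterning and meristem genes were lower in 32 of 39 in asil1-1 asil2-1, with a median log2 fold change of -0.36. Adjusted over the list alone 9 fell and 1 rose, and none passed over all genes. The falls included the auxin transporter PIN4 (-0.77 ± 0.27), the auxin response factor MP (-0.57 ± 0.20), the root patterning factors SHR (-0.66 ± 0.23) and PLT1 (-0.52 ± 0.19) and HAN (-0.80 ± 0.24), and the rise was WOX8 (1.36 ± 0.46). The camera call (adjusted p = 4.36e-06) did not hold with an estimated correlation, at adjusted p = 0.29 with an estimated correlation, and was kept with each library left out in turn. SPL factors and microRNA machinery were lower in 12 of 12 (adjusted p = 0.000966, and adjusted p = 0.29 with an estimated correlation), with AGO10 (-0.79 ± 0.24) and HEN1 (-0.48 ± 0.16) fallen when adjusted over the list alone. Cell cycle genes were lower in 22 of 26 (0.00569, and adjusted p = 0.641 with an estimated correlation), but not without replicate 1 of the double mutant or without the 2 libraries that stand apart, where the adjusted p was 0.617. Over all alternatives the adjusted p of these 3 lists reached 0.29, 0.29 and 0.641.

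Markers of the tissues around the embryo were higher in asil1-1 asil2-1. Seed coat markers were higher in 12 of 15 (median 0.53, adjusted p = 0.0186, and adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone DP1 (2.74 ± 0.76), PMEI6 (2.38 ± 0.64), PER36 (1.32 ± 0.48) and TT10 (0.64 ± 0.18) rose, and none over all genes. Endosperm markers were higher in 13 of 13 (0.0448, and adjusted p = 0.641 with an estimated correlation) and heat shock genes in 8 of 8 (0.043, and adjusted p = 0.741 with an estimated correlation), with none called, and both calls were lost with asil1-1 asil2-1 replicate 2 or 3 left out. All 3 lists were called without the 2 libraries that stand apart, seed coat markers with 10 of 15 higher (adjusted p = 0.00148, and adjusted p = 0.216 with an estimated correlation), endosperm markers with 11 of 13 (6.93e-05, and adjusted p = 0.216 with an estimated correlation) and heat shock genes with 8 of 8 (0.0135, and adjusted p = 0.689 with an estimated correlation). The endosperm gene ALE1 then rose over all genes (0.73 ± 0.14), and 3 endosperm markers adjusted over the list alone. The calls of seed coat markers, endosperm markers and heat shock genes were also lost without Col-0 replicate 3 (adjusted p = 0.0698), Col-0 replicates 1 and 3 (0.119 and 0.14) and Col-0 replicates 1 and 2 (0.11 and 0.325), and that of the seed coat without asil1-1 asil2-1 replicates 2 (0.181) and 3 (0.12). Seed storage proteins were higher in 5 of 6 without a call (adjusted p = 0.812), but this direction rested on replicate 1 of the double mutant. Without it the list was called lower (adjusted p = 0.0386). Without the 2 libraries that stand apart 5 of 6 were lower, with a median of -0.88 (adjusted p = 0.0436, and adjusted p = 0.404 with an estimated correlation), and none of them fell, over all genes or adjusted over the list alone. Over all alternatives the adjusted p ranged from 0.0386 to 0.971.

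Whether the effects of asil1-1 and asil2-1 add up was tested as the interaction on the log2 scale. AT3G26140, a cellulase-family gene, was higher in the double mutant than the sum of the single effects by 3.21 ± 0.48 (log2, SE, adjusted p = 0.0186, edgeR quasi-likelihood). It was 5.12 ± 1.47 CPM in Col-0, 2.41 ± 1.10 in asil1-1, 3.16 ± 0.882 in asil2-1 and 14.7 ± 4.35 in the double mutant (SD, n = 3 each). DREB2A differed by 2.07 ± 0.34 (adjusted p = 0.0341), at 124 ± 46.5, 69.3 ± 5.16, 49.6 ± 8 and 116 ± 27.3 CPM. The mitochondrial transcript ATMG00570 (-0.98 ± 0.17, adjusted p = 0.0718), the glutathione transferase GSTU7 (1.78 ± 0.33, 0.112) and AT2G07708 (-0.89 ± 0.17, 0.128), a gene of the mitochondrial insertion in chromosome 2 whose reads cannot be told from mitochondrial copies, did not pass. No other gene passed among 1249 at an unadjusted p under 0.05, and 9 above and 11 below 0 passed without the 2 libraries that stand apart. Without asil1-1 asil2-1 replicates 1, 2 and 3 the count was 6, 10 and 1. Without asil1-1 replicate 1 or 2, asil2-1 replicate 2 or 3, or Col-0 replicate 2 it was 0. AT3G26140 was lost with 6 of 12 libraries left out and DREB2A with 9 of 12, and over all alternatives both reached an adjusted p of 0.48.

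The wild types were compared because the second double mutant joins both backgrounds. Between Ler and Col-0, 286 genes were higher in Ler and 621 lower (edgeR quasi-likelihood, adjusted p under 0.05), or 966 and 1385 without the 2 libraries that stand apart. AT4G07825 (40.6 ± 9.09 CPM in Col-0), AT2G04378 (32.8 ± 4.50) and the DA1-related gene DAR4 (29.4 ± 5.36) had no counts in any Ler library, which makes them at least 212-fold, 171-fold and 152-fold lower against a floor of 3 counts over the group (n = 3). AT4G19240 was 116 ± 11.3 CPM in Ler and had 4 counts over the 3 Col-0 libraries, and the glycosyl hydrolase gene BGLU1 was at least 30.2-fold higher in Ler, with no count in Col-0. ASIL1 and ASIL2 did not differ, with log2 fold changes of 0.01 ± 0.20 and 0.02 ± 0.29. Alleles that differ from the reference sequence can also lose reads at mapping, so that a missing count is not a missing transcript. Leaving out single libraries gave 550 genes (without Ler replicate 2) to 634 (without Col-0 replicate 1).

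Light harvesting and photosystem genes were lower in Ler in 30 of 34, with 4 fallen over all genes, and 7 fallen and 1 risen adjusted over the list alone (adjusted p = 5.27e-05, and adjusted p = 0.517 with an estimated correlation). They were LHCB4.2 (-1.13 ± 0.15), CAB1 (-1.06 ± 0.18), PSBO2 (-0.88 ± 0.17) and LHCB2.1 (-0.84 ± 0.24). CAB1, CAB2 and CAB3 are near-identical neighbours, so that their reads can be split differently by the counting and by the ecotype. Genes of wound, touch and cold response were lower in 14 of 14 (adjusted p = 0.000175, and adjusted p = 0.471 with an estimated correlation), RD29A (LTI78) by -3.31 ± 0.73 over all genes and 6 adjusted over the list alone. All 6 measured late embryogenesis abundant genes were lower (adjusted p = 0.0191, and adjusted p = 0.471 with an estimated correlation), among them LEA7 (-3.66 ± 0.67) and LEA14 (-2.91 ± 0.72), the 2 that fell over all genes and adjusted over the list alone. Pathogen defence genes were lower in 5 of 5 (adjusted p = 0.0211, and adjusted p = 0.471 with an estimated correlation), none fallen over all genes and 2 adjusted over the list alone. Of the 10 splits of the same libraries, 9 called 4 lists or more, the real one included. The late embryogenesis list was lost with 5 of the 6 libraries left out, all but Ler replicate 3, and the pathogen list without Col-0 replicate 3 (adjusted p = 0.0543) or the 2 libraries that stand apart (0.051), and over all alternatives their adjusted p reached 0.471. Among other members, CDKB1;2 (-2.92 ± 0.41), GAPB (-1.35 ± 0.18), FWA (-2.27 ± 0.45) and TT10 (-1.13 ± 0.19) fell, and KCS18 (FAE1, 3.71 ± 0.79), which elongates seed oil fatty acids, and PMEI6 (AT2G47670, 3.41 ± 0.62) rose.

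The double mutant asil1-1 asil2-2 was compared with both wild types, and a gene counted only where it differed from both in one direction. FER2 rose by 2.33 ± 0.19 (log2, SE, the smaller of the fold changes), to 46.4 ± 6.88 CPM (SD, n = 3), against 8.14 ± 1.06 in Col-0 and 9.24 ± 0.669 in Ler. AT1G62060 rose by 3.63 ± 0.59, LRB3 by 2.30 ± 0.33, RAV2 by 1.94 ± 0.25, AT4G14730 by 1.90 ± 0.28 and ARO3, an armadillo repeat protein, by 1.79 ± 0.27. The 5 other rises, named after their values were seen, were TBL38 (1.60 ± 0.22), RUG3 (1.23 ± 0.20), AT5G64680 (0.99 ± 0.16), DI21 (0.83 ± 0.14) and AT3G27473. Besides ASIL1 and ASIL2, CAB3, a chlorophyll-binding protein, fell by 1.09 ± 0.19, though its reads may be shared with CAB1 and CAB2. edgeR's quasi-likelihood test called these 11 rises and 3 falls, with 836 genes at an unadjusted p under 0.05 and an adjusted p of 4.95e-07 for FER2, 0.000612 for RAV2 and 0.0117 for CAB3. Without the 2 libraries that stand apart there were 23 rises and 12 falls, the 14 among them. Without asil1-1 asil2-2 replicate 3 there were 26 calls and without Ler replicate 3 there were 9, and CAB3 was lost without asil1-1 asil2-2 replicate 1 or 2 or Col-0 replicate 1 or 2, and AT1G62060 without Col-0 replicate 1 or 2 or Ler replicate 1 or 3, their adjusted p reaching 0.147 and 0.101.

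**Figure D3:**
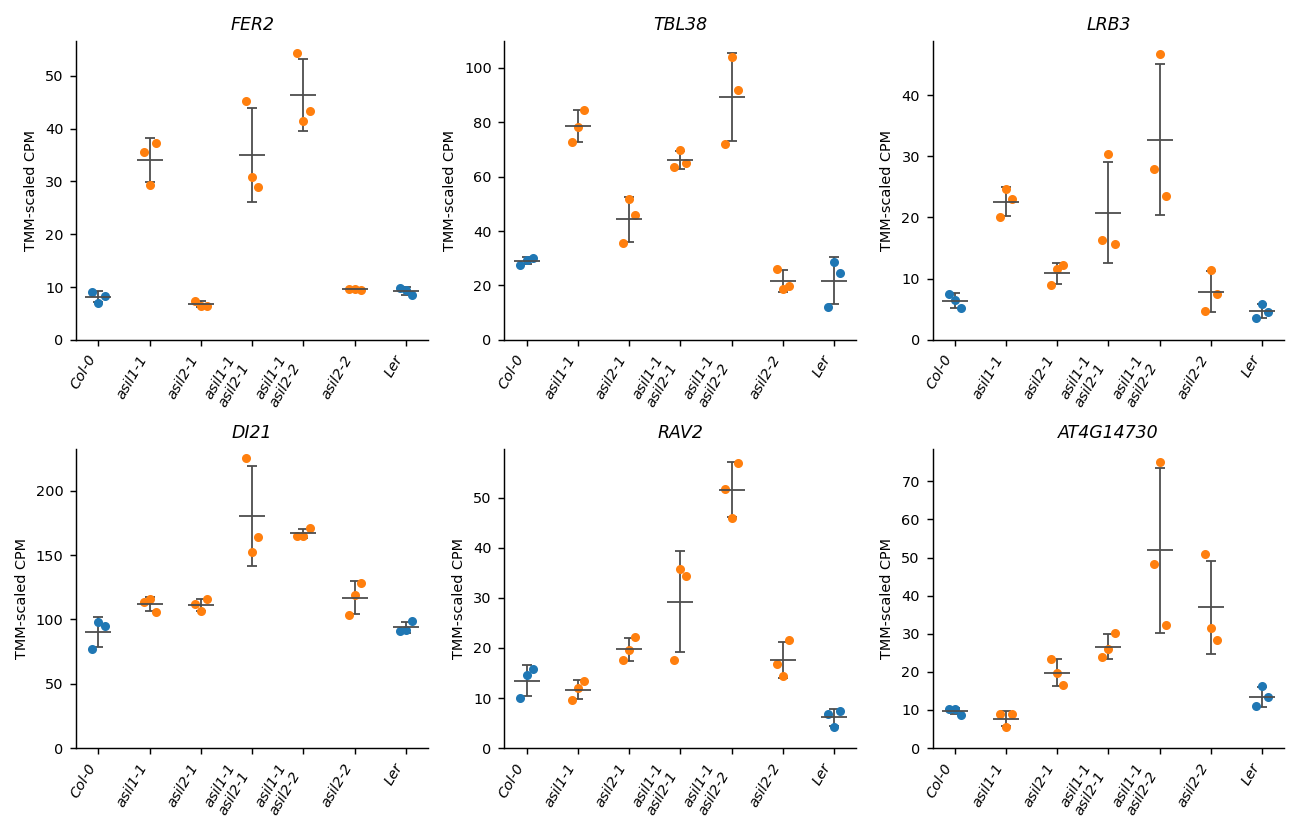
TMM-scaled CPM of 6 genes in each library, by genotype; points are libraries (wild types blue, mutants orange), and the line and bars are the mean and SD of 3. FER2 lies at 28.9 CPM or more in all 9 libraries carrying asil1-1 and at 9.82 CPM or less in the 12 others, and RAV2 and AT4G14730 are highest in asil1-1 asil2-2, at 51.6 and 51.9 CPM.

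Embryo patterning and meristem genes of asil1-1 asil2-2 were lower than in both wild types in 30 of 39, with 7 between them (median -0.22 of the fold changes nearer 0, adjusted p = 7.17e-05, and adjusted p = 0.431 with an estimated correlation). Adjusted over the list alone PLT1 fell, by 0.83 ± 0.19, and none over all genes. This call was kept with each library left out, and without the 2 libraries that stand apart it held with a median of -0.10 (adjusted p = 0.00943, adjusted p = 0.64 with an estimated correlation, and 0.128 with fry, against 0.0348 with all libraries). Seed coat markers were higher than in both in 8 of 15, with 4 between (median 0.12, adjusted p = 0.0462, and adjusted p = 0.431 with an estimated correlation), with no member risen over all genes or adjusted over the list alone, and the call was lost with 6 of 9 libraries left out, all but asil1-1 asil2-2 replicate 3, Col-0 replicate 2 and Ler replicate 2 (adjusted p = 0.05 to 0.117), and without the 2 libraries that stand apart (0.181). NCED3, of abscisic acid synthesis, fell by 0.91 ± 0.24 adjusted over its list alone, and its list was not called (adjusted p = 1). Seed storage proteins were higher than in both in 2 of 6 and between them in 4, with an adjusted p of 1.

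The mixed background of asil1-1 asil2-2 was visible along the chromosomes. For 159 genes that differed strongly between the wild types, an index was set to 0 at the Col-0 level and 1 at the Ler level. Its median was 0.39 in asil1-1 asil2-2 and 0.994 in asil2-2. On chromosome 1, which carries ASIL1, the median of 42 genes was 0.0427, and within 5 Mb of ASIL2 on chromosome 3 that of 11 genes was 0.722. The medians were 0.763 on chromosome 2, 0.51 on chromosome 3, 0.378 on chromosome 4 and 0.57 on chromosome 5.

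**Figure D4:**
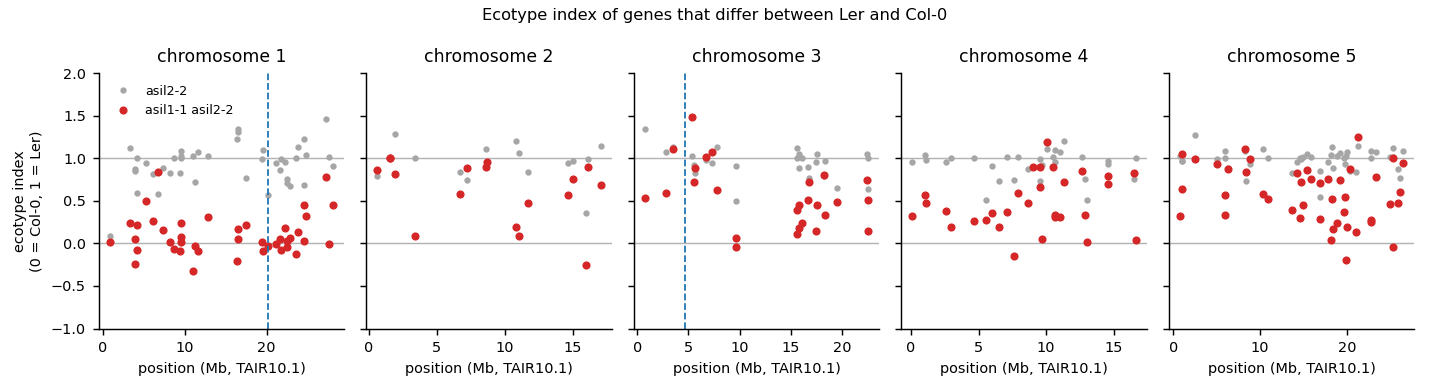
Index of 159 genes against their position (Mb, TAIR10.1), where 0 is the mean log2 CPM of Col-0 and 1 that of Ler. Red points are the median over the libraries of asil1-1 asil2-2 and grey points that of asil2-2, and dashed lines mark ASIL1 (chromosome 1) and ASIL2 (chromosome 3). Most genes of chromosome 1 lie near 0 in asil1-1 asil2-2 (median 0.0427), while asil2-2 has a median of 0.994, with exceptions such as 2A6 at 0.0929 and APD3 at 0.355.

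Calls were compared between genotypes. FER2 and ASIL1 were called in the same direction in asil1-1 and asil1-1 asil2-1, UBC11 in asil2-1 and asil1-1 asil2-1, and FER2, DI21 and ASIL1 in both double mutants, while asil1-1 and asil2-1 shared 0 calls. Independent lists of these sizes would share 0.000657, 0.000219, 0.00153 and 0.000109 genes. These comparisons share Col-0 libraries, and 20 simulations of unchanged groups against the same controls gave 0 shared calls, while 3 controls are too few to be split, so part of the overlap can come from them. The asil2-1 and asil2-2 comparisons, which share no control, had 0 calls in common (Fisher's exact test, two-sided, p = 1).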

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

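The tests on the Ler libraries and on the loss of ASIL2 below were chosen only after the results were seen, and the tests of the differences and of other splits were set beforehand.

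The effect of asil1-1 differed with and without asil2-1 for 2 genes, a difference between groups tested as an interaction (edgeR quasi-likelihood, adjusted p under 0.05). AT3G26140 differed by 3.21 (log2) and DREB2A by 2.07, each below Col-0 in both single mutants and near or above it in the double mutant. Col-0 itself spread widely for DREB2A, at 124 ± 46.5 CPM (SD, n = 3). Of 60 drawn splits of the 12 libraries, 1 gave as many genes, the real one, and the highest other gave 1, a share under 0.05. The other splits mix genotypes within groups, which can widen their spread, and the real count was 0 without asil1-1 replicate 1 or 2, asil2-1 replicate 2 or 3, or Col-0 replicate 2, so this share is not taken to exclude chance. Both genes are lost in a fit of only the 4 groups (adjusted p = 0.48, the highest over their alternatives, from 6.21e-07 and 5.95e-06).

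The response to asil2-1 in Col-0 and that to asil2-2 in Ler differed for 1 gene, again by a test of the difference, though the lower ASIL2 of the libraries labelled asil2-1 (-0.29, log2) did not pass the test. It was 2A6, at -4.10 (log2, adjusted p = 3.05e-07, edgeR quasi-likelihood), with Ler as the group apart. Of 60 drawn splits 5 gave at least 1 gene, with 2 as the highest other, so that chance is not excluded for the number of genes.

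Many of the genes that separate asil2-2 from Ler separate Ler from every other library. In 7 of the 12 calls besides ASIL2 the 3 Ler libraries lay beyond all 18 others, 2A6 at 1.07 ± 0.375 CPM against 17.5 to 35.1 (SD, n = 3), and AGD9 and MYC3 are neighbours on chromosome 5, which 12 random genes would give with a permutation p of 0.00693. The Ler stock sequenced may therefore differ from the one behind asil2-2 at some loci. For 5 calls asil2-2 lay beyond all 18 others, or asil1-1 asil2-2 was called the same way against both wild types, among them RAV2, AT4G14730 and DDB1B, and HDG2 and VLN5 lay the same way there without a call, so that an effect of ASIL2 stays open for these. RAV2 and VLN5 are also among the 7. In asil1-1 asil2-2, DDB1B was at 29.9, 90.8 and 48.7 CPM in replicates 1, 2 and 3, against 80.5 to 87.9 in Col-0, although ASIL2 was at 0 CPM in replicate 2, and AT2G34655 was at 1.036, 0 and 17.59 CPM there and at 29.3 CPM in asil1-1 asil2-1 replicate 1. AT4G14730 was at 16.4 to 30.1 CPM in the 6 libraries labelled asil2-1 as well, against 5.4 to 16.2 in the 9 without an asil2 mutation, which a difference of the Ler stock does not predict, though with all libraries it passed in neither asil2-1 (1.02, adjusted p = 1) nor asil1-1 asil2-1 (1.46, 0.0918), and without the 2 libraries that stand apart only in the latter. With 1 allele in Ler and 1 Ler stock the 2 cannot be told apart for the other genes.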

How the results depend on the processing

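The tests without the 2 libraries that stand apart and those with limma-voom and library weights were chosen after the results were seen. Alternatives were run on the genes named by the rule and on the lists, not on every called gene. Of these, none that was called changed direction, but tests without a call did. With list directions written as 1 (up) and -1 (down), 166 list tests moved to the other direction. Of these, 164 had no call either way and 2 were called in the new direction. Both are seed storage proteins in asil1-1 asil2-1, which went from 1 to -1 without asil1-1 asil2-1 replicate 1 (adjusted p = 0.0386) and without both libraries that stand apart (0.0436), against 0.812 with all. Counts of calls stayed within 1.5 times their value in 168 cases and moved in 133. Over all genes named, 916 tests kept their side of the threshold, 33 gained it and 152 lost it, and for lists that kept their direction 1616 kept it, 38 gained it and 122 lost it. The tests of ASIL1 and ASIL2 kept direction and side in 91 cases. ASIL2 in asil1-1 asil2-1, not called, moved from 0.00 to below 0 in 5, among them -0.02 without the filter on low counts and -0.00 with a replicate block, with -0.17 to 0.12 over the libraries left out. In 1 case a call was lost, for ASIL1 in asil1-1 asil2-1 with only the compared groups (log2 fold change -3.25, adjusted p = 0.0598, against 1.89e-28 to 0.0598 over its alternatives). There fewer libraries give the estimate of spread, and replicate 1 of asil1-1 asil2-1, which stands apart, is among them. The same setting gave more calls in asil1-1, in asil2-2 and between the wild types, and the cause of the loss was not tested.

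Without both libraries that stand apart, calls numbered 35 in asil1-1, 48 in asil2-2, 26 in asil1-1 asil2-1, 35 in asil1-1 asil2-2, 2351 between the wild types, 20 for the interaction and 11 for the allele difference. The double mutants then shared 12 calls and asil1-1 shared 6 with asil1-1 asil2-1, and 1 list was called in asil2-2 and 1 in asil1-1 asil2-2. With library weights in limma-voom, the counts were 75 in asil1-1, 15 in asil2-1, 47 in asil2-2, 141 in asil1-1 asil2-1, 43 in asil1-1 asil2-2, 2711 between the wild types, 113 for the interaction and 15 for the allele difference. Shared calls were then 1 for asil2-1 and asil2-2, 23 for the double mutants and 16 for asil1-1 and asil1-1 asil2-1, and 0 lists were called in asil2-2 and 1 in asil1-1 asil2-2. The weights were lowest, 0.083 and 0.305, for the 2 libraries that stand apart. In edgeR without these 2, genes at an unadjusted p under 0.05 went from 453 to 1378 in asil1-1, from 316 to 1212 in asil2-1 and from 471 to 1459 in asil2-2. They went from 301 to 1094 for the allele difference, but from 2942 down to 2292 in asil1-1 asil2-1. The fit with all libraries thus gave fewer low p in most comparisons. Without these 2, the numbers of asil1-1, asil2-1, asil2-2 and the allele difference lay above the share of 0.05 of the 18332 genes then tested. Their low numbers with all libraries therefore do not show that no genes differ.

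DESeq2 called 17 genes in asil1-1, 4 in asil2-1, 24 in asil2-2, 273 in asil1-1 asil2-1, 44 in asil1-1 asil2-2, 27 for the interaction and 11 for the allele difference. The double mutants shared 21 calls, asil1-1 and asil1-1 asil2-1 shared 9, and 4 lists were called in asil2-2. With only the compared groups in the fit there were 24 calls in asil1-1, 27 in asil2-2, 0 in asil1-1 asil2-1, 2150 between the wild types, 0 for the interaction and 10 for the allele difference. All 3 overlaps with asil1-1 asil2-1 that had calls were then 0 (with asil1-1 asil2-2, asil1-1 and asil2-1), and 2 lists were called between the wild types. In edgeR 2942 genes of asil1-1 asil2-1 and 1249 of the interaction had an unadjusted p under 0.05 with all libraries in the fit.

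RLE scaling gave 2 calls for the allele difference and 5 shared by the double mutants. Without the filter on low counts 1 list was called in asil2-2 and 2 between the wild types. The double mutant asil1-1 asil2-2 had 417 calls against Col-0 alone (230 up, 187 down), 529 against Ler alone (395 up, 134 down) and 343 against the mean of both (276 up, 67 down), where the call needs less than in both. With an estimated correlation 1 list was called in asil1-1 and 0 in each of the other 5 comparisons. With fry 1 was called in asil1-1, 0 in asil2-1, 0 in asil2-2 and 3 in asil1-1 asil2-1. Other causes were not tested.

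The labels number replicates alike, but the numbers were not taken as pairs, since no comparison had all correlations between deviations of same-numbered libraries over 0.1 (7 of 21 were, -0.122 to 0.163). As a hint from the data, 15 of 21 were best with their own number, all 3 of them in asil1-1 asil2-1 against Col-0, in asil1-1 asil2-2 against Col-0 and in Ler against Col-0. With a replicate block there were 4 calls in asil2-1 and 20 in asil1-1 asil2-1, 9 shared by the double mutants, 6 shared by asil1-1 and asil1-1 asil2-1, and 1 list in asil1-1 asil2-2.

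With each library left out in turn, calls ranged from 2 to 4 in asil1-1, 0 to 0 in asil2-1, 5 to 10 in asil2-2, 2 to 239 in asil1-1 asil2-1, 9 to 26 in asil1-1 asil2-2, 550 to 634 between the wild types, 0 to 10 for the interaction and 1 to 2 for the allele difference. Shared calls ranged from 2 to 10 for the double mutants, 2 to 4 for asil1-1 and asil1-1 asil2-1, and 0 to 1 for asil2-1 and asil1-1 asil2-1. Called lists ranged from 4 to 9 in asil1-1, 1 to 9 in asil2-1, 0 to 6 in asil2-2, 3 to 8 in asil1-1 asil2-1, 1 to 2 in asil1-1 asil2-2 and 3 to 4 between the wild types. At a depth of 1.49 M (1000000 counts), asil1-1 asil2-2 replicate 2 listed 17173 models against 20666 to 22471 in the others.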

Other observations

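Apart from the counts of other splits, which were set beforehand, the tests in this part were chosen only after the results were seen.

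Among the 34 genes that rose in asil1-1 without the 2 libraries that stand apart, some were picked here after their values were seen, with no test of a shared function. The protease LON1 rose by 0.44 ± 0.08 (log2, SE), the elongation factor gene AT4G02930 by 0.51 ± 0.09, AT2G45030 by 0.67 ± 0.14 and the mitochondrial transcripts ATMG00160 and ATMG00510 by 0.48 ± 0.08 and 0.43 ± 0.09 (edgeR quasi-likelihood, adjusted p = 0.0151 to 0.0441). In asil1-1 asil2-1, RAV2 (1.37 ± 0.21), AT4G14730 (1.53 ± 0.26), TBL38 (1.21 ± 0.21), LRB3 (1.83 ± 0.30) and AT1G62060 (2.91 ± 0.59) then rose as well, all of them genes that also rose in asil1-1 asil2-2. In asil2-2 the fall of AGD9 and MYC3 was then joined by that of their neighbours UBP21 (-1.06 ± 0.10) and AT5G46730 (-1.49 ± 0.29).

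With all libraries, 81 of 92 measured genes of the mitochondrial genome were higher in asil1-1, with a median log2 fold change of 0.263 (camera adjusted p = 8.59e-15, and adjusted p = 0.0596 with an estimated correlation). The other genotypes with asil1-1 did not share this call, with 47 of 92 higher in asil1-1 asil2-1 (median 0.0093, adjusted p = 0.24), and in asil1-1 asil2-2 23 against Col-0 (-0.177, adjusted p = 0.0804) and 33 against Ler (-0.165, adjusted p = 0.24). Genes of the chloroplast genome were higher in asil1-1 as well, in 65 of 70 (median 0.0945, adjusted p = 0.0016, and adjusted p = 0.861 with an estimated correlation). They were also higher in asil1-1 asil2-1, in 48 of 70 (median 0.154, camera adjusted p = 0.00183). In asil1-1 asil2-2 they were higher in 54 against Col-0 (0.112, adjusted p = 0.0391) and in 46 against Ler (0.0674, adjusted p = 0.227). None of these held with an estimated correlation (adjusted p = 0.861 and 0.864). Whether mitochondrial function rose in the nucleus too was tested on 132 nuclear genes named for mitochondria, of which 84 were higher with a median of 0.0467 (adjusted p = 0.0391, and adjusted p = 0.861 with an estimated correlation). This leaves open whether a rise of mitochondrial function could lie behind it, as none of the 92 passed over all genes, and reads of the mitochondrial copy in chromosome 2 cannot be told apart from them.

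The outer seed coat markers PMEI6, DP1, PER36 and MUM4 were higher in asil1-1, though none was called over all genes. MUM2 (-0.58) and SBT1.7 (-0.079, at 878 CPM in Col-0) of the same layer were lower. The embryos were dissected by hand from seeds, so RNA of the coat may have been carried along despite washing and Percoll. The whole coat would raise all its layers, while outer-layer minus endothelium markers differed by 1.61 (SE 0.491, mean log2 CPM, n = 3 each) between asil1-1 and Col-0, which repeats the pattern, as the layers were divided after these values were seen. The difference was 0.564 (SE 0.587) in asil1-1 asil2-1 against Col-0, where all 5 endothelium markers were higher, and 1.35 (SE 0.648) in asil1-1 asil2-2 against Ler, so that RNA of the whole coat stays open. The outer layer alone, if carried along in asil1-1 asil2-2 too, would raise all of its markers there against Ler. Their median was 0.603, from 0.0674 to 3.55, against 2.33 for the 5 genes risen in asil1-1. The choice of wild type matters, as PMEI6 differed by 0.898 against Ler but by 4.31 against Col-0. SBT1.7 differed by 0.514 against Ler and by -0.157 against Col-0. The outer-layer markers lay on both sides of the bound set for the test. The test cannot decide, since the 5 risen genes set no level for coat RNA, which need not be carried along in another genotype. Whether coat RNA adds to the counts of these 5 genes themselves was not tested. The mean log2 CPM of the 6 outer-layer markers was 4.326 to 4.952 in the 9 libraries carrying asil1-1 and 3.135 to 4.18 in the 12 others. The higher level was thus shared by both double mutants, although the layers were divided after the asil1-1 values were seen. RNA of the outer layer stays open, as does expression of these genes in the embryo itself after loss of ASIL1.

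Replicate 1 of asil1-1 asil2-1 stands apart from all other libraries. AT5G18610 took 45.7% of its counts, and without that locus its correlations with the other libraries ran from 0.684 to 0.76, against 0.683 to 0.76 with it, but 1 locus among 18269 cannot move such a correlation, so a few abundant genes stay open as the cause. A library of a genotype without asil1-1 is argued against by ASIL1 at 2.73 CPM, against 32.4 CPM or more without the mutation. Loci with almost no reads elsewhere took 0.92% of its counts, against 0.0219% to 0.0706%, and there counts followed exon length with a Spearman rho of 0.346, against 0.0764 to 0.276 in the others, between the bounds set for genomic DNA, which stays open. No biological explanation was tested, since the genotype's other replicates lack the pattern.

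The double mutant asil1-1 asil2-2 may carry a patchwork of Col-0 and Ler chromosome segments. Over 159 genes that separate the wild types, neighbours had closer index values than permuted ones, with p = 1e-05, the smallest that the permutations can give. Values were permuted over all chromosomes, so the low values of chromosome 1 (median 0.0427) may lower this p without segments within chromosomes. The median index was 0.0344 for 19 genes within 5 Mb of ASIL1, from the Col-0 parent, and 0.722 for 11 genes within 5 Mb of ASIL2, from the Ler parent. Segments fixed for either wild type would give values near 0 or 1. The quartiles were -0.0395 and 0.219 on chromosome 1, but 0.283 and 0.715 on chromosome 4 and 0.316 and 0.843 on chromosome 5. Fixed segments alone do not give such values between the wild types.

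UBC11 was lower in both genotypes with asil2-1, and a difference carried by that line, apart from any loss of ASIL2 (whose counts did not pass the test there), is a candidate explanation. In asil2-2 against Ler the log2 fold change of UBC11 was 0.071 (95% interval -0.30 to 0.44), while UBC11 fell by 1.33 in asil2-1. UBC11 starts at 2641012 and ASIL2 at 4706802 on chromosome 3 (TAIR10.1), so that a variant linked to the allele is possible and was not tested.

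Other splits of the same libraries were counted. For 3 against 3 libraries the 10 splits are too few for a share under 0.05, but they can show a high share. There, asil1-1 had 6 calls and the highest other split 0 (lists 6 and 6, reached by 2 of the 10 splits), asil2-1 had 2 and 0 (lists 8 and 7, reached by 1), and asil2-2 13 and 0 (lists 2 and 6, reached by 8). The double mutant asil1-1 asil2-1 had 4 and 0 (lists 6 and 4, reached by 1), and Ler 907 and 0 (lists 4 and 7, reached by 9). The numbers of lists called in asil1-1, asil2-2 and Ler were thus reached or passed by other splits, so that chance is not excluded for them. For asil1-1 asil2-2 against both wild types, 3 of 60 drawn splits gave 14 calls or more, the real one included, and the highest other gave 209, so that chance is not excluded. In the longer first draw the share was under 0.05, so this verdict turned when the draw was shortened after its counts had been seen. A split that calls 209 genes points to a structure of the samples, which may be the ecotypes and was not tested further. These splits shuffle Col-0 and Ler libraries, which differ in 907 genes, across the groups. The share therefore does not measure chance alone and decides nothing here. For the lists of asil1-1 asil2-2, 17 of 60 splits gave 2 or more and the highest other gave 5, and chance is not excluded either.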
